A study of Mus musculus with 2 samples.

How the data were processed

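The data were single-nucleus RNA-seq libraries made by Drop-seq from the cortex of adult male wild-type C57BL/6J mice. Nuclei had been sorted by fluorescence on NeuN, an antigen of neuronal nuclei, into a NeuN-positive and a NeuN-negative library. Each group held 1 library, and the labels do not say how many animals went into it. The series also profiles cytosine modifications, which were not analysed here.

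The deposited tables held whole-number UMI counts per gene and nucleus barcode, with no normalization. STAR 2.5.2a, Seurat 3.2.3 and the mm10 build are named in the submitters' processing notes, without a role for each. How the authors chose barcodes is not given in the sources used here. The tables held 6250 NeuN-positive and 2000 NeuN-negative barcodes, with 30158 genes listed in either. Gene positions came from the GENCODE M21 annotation of the same build, matched by symbol, where 28429 of the 30158 genes were found. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes could share UMIs.

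Nuclei with at least 300 detected genes and at most 10% mitochondrially encoded UMIs were kept, which left 6250 NeuN-positive and 366 NeuN-negative nuclei. Doublets were scored per library with Scrublet as built into scanpy 1.11.5, at an expected rate of 0.05. It called 14 of 6250 NeuN-positive nuclei (0.224%), too few for the caller to have worked there, and 13 of 366 NeuN-negative nuclei. These were removed, leaving 6236 and 353 nuclei. Doublets were therefore not reliably removed from the NeuN-positive nuclei. No cluster had more markers of another class than of its own among its top 10 genes, so none was removed as mixed. Markers of another class were among these genes in 2 clusters, which were kept.

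Both libraries were clustered together without batch correction, since library and sort were the same variable. Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes among those in at least 3 nuclei were used, followed by 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (python-igraph 0.11.9). All 301 genes of the 17 gene lists and all mitochondrially encoded genes were kept out of these features. Clusters were named from 32 marker sets of 216 genes, of which 8 were not found in the tables. A name needed at least 3 markers with at least 3 UMIs and a level 2-fold over clusters of other classes.

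UMIs were summed over nuclei of a library or class and expressed as CPM, the count scaled to the total of that library or class. With 1 library per group no test across libraries was possible, and no p-value, standard error or number of changed genes was computed. Shares carry exact Clopper-Pearson 95% intervals, levels exact Poisson intervals, and ratios exact conditional intervals. Intervals of list medians came from 1000 Poisson draws of the counts. Draws of 0 were set to 3 UMIs, so these intervals can lie off-centre where counts are low. All intervals cover counting error only, not the spread between animals or sorts. A sum of 0 was set to 3 UMIs, which makes the ratio a bound. List members needed 50 UMIs over both sums. A list median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

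The rules for naming genes, the lists and most alternatives were fixed before the data were examined. Rbfox3 came first. Between libraries, the 10 largest ratios each way were named among genes with at least 100 CPM in the higher library, leaving out predicted genes, mitochondrial genes and clone names. Between excitatory-like and inhibitory-like nuclei the same floor was used without cell type markers. There each gene was measured on classes clustered from the other random set of genes, and these classes matched the main ones for 99.7% and 99.8% of nuclei. From each list the 2 highest and 2 lowest ratios could be named. Some genes that these rules name are not reported here.

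The computations were tested on simulated data. For the library comparison, run on 11829 genes with 200 changed 4-fold, 179 changed genes passed the UMI minimum and 96.6% of those had the right direction. For the neuron classes, run on 11618 genes, 189 passed and 100% had the right direction. The exact intervals of gene ratios held the true value for 97.3% and 96.4% of genes. The intervals of list medians were not tested in this way. Of 100 unchanged lists of 20 genes, 9 and 3 fell outside the central 95% of random lists. Clustering of 1133 simulated nuclei named 98.7% correctly. They were drawn from the summed profiles of excitatory-like, inhibitory-like, astrocyte-like, oligodendrocyte-like and OPC-like nuclei as named here. High recovery was therefore largely built in, and it does not show that the names of real nuclei are right.

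Alternatives were minima of 500 and 800 genes, doublets kept, Leiden resolution 0.5, each library clustered alone, the mean of the CPM of each nucleus, scaling without mitochondrial genes and Malat1, TMM factors (edgeR 4.0.16 in R 4.3.3), no UMI minimum with 0.5 added to each count, and nuclei thinned to 500 UMIs. Minima of 200 and 100 genes with each library clustered alone, and removal of the highest 5% of Scrublet scores, were added after seeing the data. Barcodes with fewer than 100 detected genes were not used here.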

Results

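Single-nucleus RNA-seq counts were analysed for nuclei of adult mouse cortex sorted on NeuN. The NeuN-positive library held 6250 barcodes with 11731430 UMIs, a median of 1675 UMIs and 1007 detected genes per barcode. The NeuN-negative library held 2000 barcodes with 600449 UMIs, a median of 228 UMIs and 166 genes. After filtering, 6236 and 353 nuclei remained, with 11686960 and 253132 UMIs. The kept nuclei had median depths of 1674 and 626 UMIs. There was 1 library per group, so no difference below has a replicate check.

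The first comparison asked which cell classes each sort gate held. In the NeuN-positive library 6221 of 6236 nuclei (99.8%, 95% interval 99.6 to 99.9) fell in neuronal clusters. Its deposited barcodes held at least 745 UMIs and 509 genes, so this share need not hold for shallower nuclei of the gate. Excitatory-like nuclei made up 5650 of these 6221 (90.8%, 90.1 to 91.5), and inhibitory-like nuclei 521 (8.37%, 7.70 to 9.09). Another 50 nuclei (0.802% of the library, 0.596 to 1.06) formed a striatal spiny neuron-like cluster led by Rgs9, Penk and Adcy5. In the NeuN-negative library 153 of 353 nuclei were astrocyte-like (43.3%, 38.1 to 48.7), 98 oligodendrocyte-like (27.8%, 23.2 to 32.7), 74 OPC-like (21.0%, 16.8 to 25.6) and 12 microglia-like (3.40%, 1.77 to 5.86). OPCs are oligodendrocyte precursor cells.

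Among the 10 excitatory-like clusters, names of cortical layers were reached for 8. The L2/3-like nuclei were the most numerous, with 2076 of 6236 nuclei (33.3%, 32.1 to 34.5). L6 corticothalamic (CT)-like nuclei followed with 737 (11.8%), L5 intratelencephalic (IT)-like with 591 (9.48%), L4-like with 347 (5.56%), L5 extratelencephalic (ET)-like with 208 (3.34%), L6b-like with 147 (2.36%) and L6 IT-like with 146 (2.34%). A cluster led by Rorb and Pld5 with 917 nuclei, and a cluster led by Galnt14 with 481, carried excitatory markers but no layer name. Of the inhibitory-like nuclei, 173 were Sst-like (2.77% of the library). The remaining 348 lay in a cluster led by Adarb2 and a cluster led by Erbb4 and Kcnmb2, without a subtype name.

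Each gate also held a few nuclei of the other kind. In the NeuN-positive library 15 of 6236 nuclei (0.241%, 0.135 to 0.396) lay in glial clusters, 7 of them microglia-like, 5 astrocyte-like, 2 OPC-like and 1 oligodendrocyte-like. Pooled, these 15 nuclei carried Syt1 at 5671 CPM and Snhg11 at 4950 CPM, against 5861 and 5227 CPM in the neurons of the library, although 1 of them held 1 UMI of Syt1, Snhg11 and Kcnip4 among 2322, and the share was 0% when the library was clustered alone. In the NeuN-negative library 16 of 353 nuclei (4.53%, 2.61 to 7.26) were neuronal, 9 inhibitory-like and 7 excitatory-like. The 7 held no Slc17a7 UMI among 9274, which allows up to 323 CPM. Excitatory-like nuclei of the NeuN-positive library were at 171 CPM, so this absence decides nothing. The depth gap and the gene minimum bear on these shares: with a minimum of 100 genes, 617 of 1450 NeuN-negative nuclei (42.6%, 40.0 to 45.1) were oligodendrocyte-like, 283 (19.5%, 17.5 to 21.7) microglia-like, 274 (18.9%) astrocyte-like and 144 (9.93%) OPC-like. Another 22 (1.52%, 0.953 to 2.29) were neuronal. They formed a single cluster that took the inhibitory-like name as a whole, so any excitatory nuclei in it were not counted apart. A further 13 (0.897%, 0.478 to 1.53) lay in a cluster without a name.

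**Figure D1:**
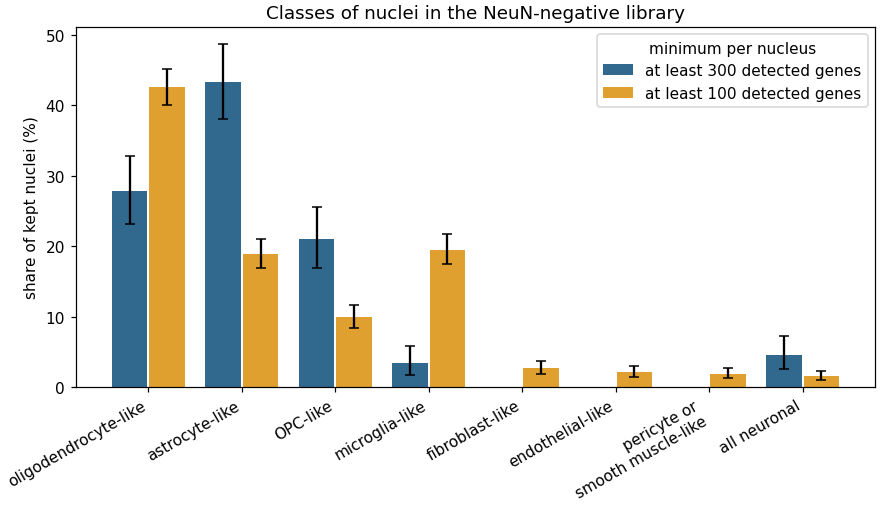
Share of kept nuclei in percent (vertical axis) for each class of the NeuN-negative library (horizontal axis), at a minimum of 300 detected genes (353 nuclei) and of 100 (1450 nuclei, that library clustered alone), with exact 95% binomial intervals as error bars. Oligodendrocyte-like nuclei were 27.8% and 42.6%, and the fibroblast-like, endothelial-like and pericyte or smooth muscle-like classes formed clusters only at the lower minimum.

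The second comparison set the summed counts of the libraries against each other. Rbfox3 (chromosome 11, 118489762 to 118911597 in mm10) encodes the NeuN antigen and checks the labels. It stood at 207 CPM (2423 UMIs) in the NeuN-positive and 51.4 CPM (13 UMIs) in the NeuN-negative library, a log2 ratio of 2.01 (95% interval 1.24 to 2.92). By class it was at 216 CPM in excitatory-like, 108 in inhibitory-like, 37.7 in astrocyte-like and 15.1 in oligodendrocyte-like nuclei. The 16 neurons of the NeuN-negative library held 7 Rbfox3 UMIs, against 4.77 at the level of the NeuN-positive neurons.

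The 10 largest ratios toward the NeuN-positive library were those of Nrn1 (neuritin, chromosome 13), Cpne9, Chgb (secretogranin-1), Nptxr (a neuronal pentraxin receptor), Plekhg5, Kcnj6 and Kcnj9 (inwardly rectifying potassium channels), Camkk2, Ptk2b and Prmt8. Their log2 ratios ran from 5.55 for Nrn1 (3.07 to 10.9) to 4.41 for Prmt8 (2.56 to 7.46). Each rested on 1 or 2 UMIs in the NeuN-negative library. A gene with no UMI there was ranked as if it held 3. Genes seen only in the NeuN-positive library could therefore rank below these 10, which need not be the most restricted to it. On the other side stood Aspa, which degrades N-acetylaspartate in oligodendrocytes, with a log2 ratio of -9.07 (-10.1 to -8.18), Hepacam (-8.74), the glutamate transporter Slc1a3 (-8.53, -8.96 to -8.12), Gjc3 (-8.37), the myelin gene Mog (-8.34), Slc7a10 (-8.21), Prr5l (-7.98), Slco1c1 (-7.94), Bcas1 (-7.85) and St18 (-7.72). Aspa was at 0.941 and 506 CPM.

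Ion channel and receptor lists lay toward the NeuN-positive library. For voltage-gated sodium and calcium channels 18 of 20 members were at least 2-fold higher there and none at least 2-fold lower, with a median log2 ratio of 2.41 (1.96 to 2.46), above all 10000 random lists. Scn3b (3.65, 1.16 to 8.95) and Cacna1b (3.34) were its highest members. GABA receptors had a median of 1.88 (percentile 99.97), with Gabrg1 at -2.99. Metabotropic glutamate receptors had a median of 1.80 (percentile 98.5), with Grm7 at 2.03 and Grm3 at -1.65. Synaptic adhesion genes had a median of 1.53 (percentile 99.9), with Nlgn3 at -0.51 and Slitrk3 at 3.37 (0.89 to 8.68), and voltage-gated potassium channels 1.38 (percentile 99.9), from Kcnn3 at -2.14 to Kcnh1 at 4.15. Ionotropic glutamate receptors had a median of 0.85 (percentile 95.6), with Grin2a at 3.54 and Grin2b at 3.19 against Grin2c at -6.83 and Grin3a at -2.32. A minimum of 500 genes moved the median of all genes by -0.37. The medians were then 1.36 for sodium and calcium channels, 1.21 for GABA receptors and 0.95 for potassium channels. They were 0.67 for metabotropic and 0.42 for ionotropic glutamate receptors. Each of these medians fell by more than the median of all genes. The neuronal share of the NeuN-negative library was also higher at that minimum. Whether that share lowered these medians was not tested.

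Immediate early genes, which respond to neuronal activity, had a median of 1.31 (0.67 to 1.74, percentile 99.99), with 10 of 17 members at least 2-fold higher in the NeuN-positive library. Egr1 (3.44, 1.59 to 6.49) and Nr4a3 (3.10, 0.61 to 8.41) were highest, and 6 members had no UMI in the NeuN-negative library and stand at their bound. With these 6 above all other members the median would be 2.37. At a minimum of 500 genes the median was 0.30. Fewer NeuN-negative UMIs move the bound there, and the neuronal share of that library was higher. Which of these lowered the median was not tested. Nuclear long noncoding RNAs had a median of 1.79 (percentile 99.8), and of 0.81 at a minimum of 500 genes. Snhg11 (3.35) and Miat (3.07) were higher in the NeuN-positive library, while Neat1 (-7.43) and Malat1 (-1.06) were higher in the other. Mitochondrially encoded transcripts had a median of 0.90 (percentile 95.5), lower at a minimum of 100 genes and higher under TMM scaling.

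The cholesterol and myelin lipid list lay toward the NeuN-negative library, and so did the 2 measured members of the immune list. For cholesterol and myelin lipid synthesis 10 of 19 members were at least 2-fold higher there and none in the other, with a median of -1.07 (-1.61 to -0.68, percentile 0.07). Fa2h (-7.22) and Ugt8a (-4.90), enzymes of myelin lipids, were lowest. Of 18 listed phagocytosis and innate immune receptors only Mertk (-7.35) and Apbb1ip (-4.08) reached 50 UMIs. Mertk was at 1537 CPM in astrocyte-like nuclei, so it does not stand for immune cells alone. The respiratory chain (median 0.19, percentile 83.5), ribosomal protein (-0.08, percentile 43.5) and histone modifier lists (-0.04, percentile 43.6) lay within the random lists, with Ezh2 at -1.73 and Chd5 at 1.81 in the last. At a minimum of 500 genes the ribosomal protein median was -0.87.

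Of the lists on DNA methylation, writers and TET oxidation lay within the random lists between libraries. Readers and corepressors lay low among the random lists. DNA methylation writers and maintenance had a median of 0.13 (-0.45 to 0.49, percentile 78.2) over 4 members, the 3 with UMIs in both libraries within 2-fold, and of -0.63 at a minimum of 500 genes. Hells had no NeuN-negative UMI and stands at its lower bound. TET oxidation and base excision had a median of -0.34 (-0.70 to 0.10, percentile 27.9) over 16 members, where Tet1 (-2.02, -2.65 to -1.32) and Idh2 (-1.70) were lowest. Apex1, Gadd45b and Idh3a had no NeuN-negative UMI and entered at their lower bound, and with them above all other members the median would be -0.0071. Readers and corepressors had a median of -0.48 (-0.54 to -0.01, percentile 4.4), with 17 of 18 members within 2-fold. Under TMM scaling, which moved the median of all genes by 0.60, the TET median was 0.26 and the readers' median 0.12, a shift that the random lists share.

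**Figure D2:**
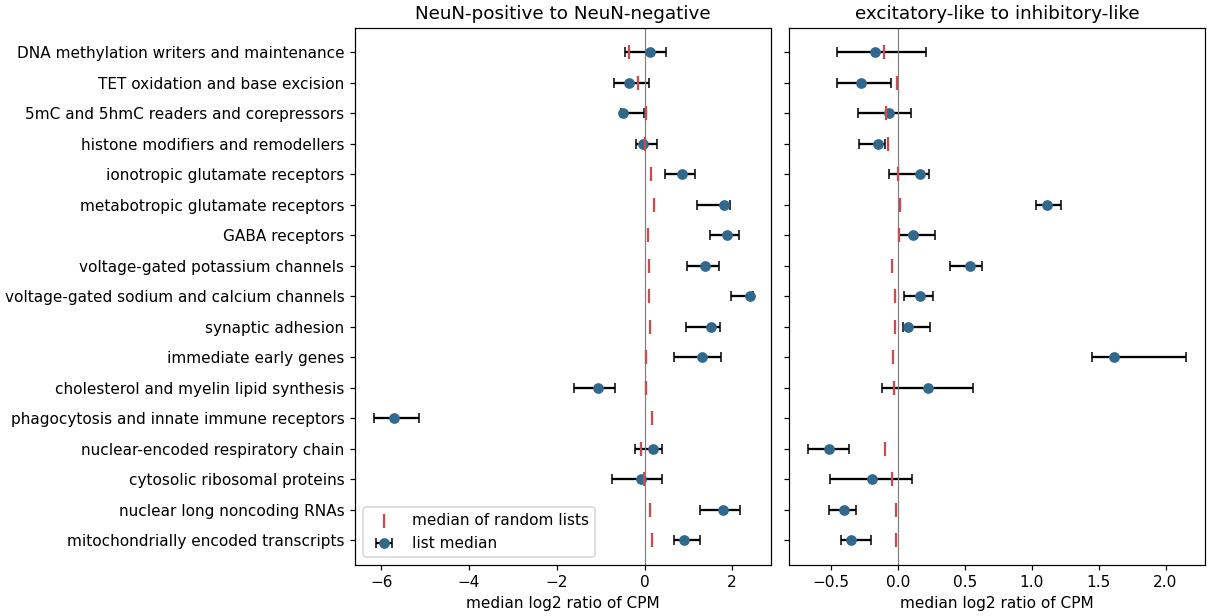
Median log2 ratio of CPM (horizontal axis) of each gene list (vertical axis), between libraries on the left and between neuron classes on the right; bars are 95% intervals from Poisson draws of the counts, red ticks the median of 10000 random lists. Sodium and calcium channels reached 2.41 on the left and immediate early genes 1.62 on the right, and the immune list had no measured member on the right.

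The third comparison, within the NeuN-positive library, set 5650 excitatory-like against 521 inhibitory-like nuclei. Immediate early genes stood furthest apart, with a median log2 ratio of 1.62 (1.45 to 2.16, percentile 100). Of 17 members 14 were at least 2-fold higher in excitatory-like nuclei and none in inhibitory-like nuclei, led by the neurotrophin Bdnf (3.40, 2.03 to 5.28) and Dusp1 (3.25, 0.74 to 8.56), with Jun (0.77) and Fos (0.86) lowest. Fosb and Egr4 had no UMI in inhibitory-like nuclei and stand at their bound. Metabotropic glutamate receptors had a median of 1.11 (1.03 to 1.22, percentile 99.8), with Grm2 at 3.71 (1.21 to 9.02) and Grm3 at 1.97. Potassium channels had a median of 0.53 (percentile 99.99), although Kcnc1 (-2.82) and Kcnc2 (-2.64), channels of fast-spiking neurons, were higher in inhibitory-like nuclei.

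Other lists held members that went opposite ways. Among ionotropic glutamate receptors (median 0.16, percentile 83.6) Grin3a (-4.04) and Grik1 (-3.39) were higher in inhibitory-like nuclei and Grik4 (1.50) in excitatory-like nuclei. Sodium and calcium channels (0.16, percentile 91.2) ranged from Cacna2d2 at -4.45 to Cacna2d1 at 1.67. GABA receptors (0.11, percentile 74.5) ranged from Gabrg3 at -1.28 to Gabra2 at 1.18, and synaptic adhesion genes (0.07, percentile 75.9) from Cntnap2 at -1.71 to Ptprd at 1.44. The nuclear-encoded respiratory chain had a median of -0.52 (-0.68 to -0.37, percentile 0.2), with Ndufb8 at -1.38. Mitochondrially encoded transcripts (-0.35, percentile 6.32) and nuclear long noncoding RNAs (-0.41, percentile 2.52) lay the same way, the latter with Pvt1 at -1.76 and Miat at 1.38. Cholesterol and myelin lipid synthesis (0.22, percentile 87.7), ribosomal proteins (-0.20, percentile 24.7) and histone modifiers (-0.15, percentile 25.2) lay within the random lists. The histone modifier median was 0.08 under TMM scaling.

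Measured on classes from the other set of genes, the genes with the largest ratios toward excitatory-like nuclei were the calcium pump Atp2b4 (3.16, 2.35 to 4.12), Meis2 (3.02), Itpka (3.02), Cpne9 (3.00), Fam19a1 (3.00), Baiap2 (2.88), Ptk2b (2.83), Nrn1 (2.67), the syntaxin Stx1a (2.58) and Ngef (2.40). Toward inhibitory-like nuclei they included the potassium channel subunit Kcnmb2 (-6.36, -6.64 to -6.10), Kcnip1 (-5.77), Adarb2 (-5.64), Vwc2 (-5.53), the transcription factor Sox6 (-5.49), Sox2ot (-5.21), Ankrd55 (-5.13), Pde5a (-4.88) and Pde11a (-4.75). Kcnmb2 was at 12.1 and 1000 CPM.

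The series concerns 5mC and 5hmC, so the levels of their writers, oxidases and readers were taken per class, with neurons from the NeuN-positive and glia from the NeuN-negative library. Dnmt3a (chromosome 12, 3806007 to 3914443), a de novo DNA methyltransferase, was at 219 CPM in excitatory-like (95% interval 211 to 228), 219 in inhibitory-like (189 to 252), 217 in astrocyte-like (137 to 325) and 151 CPM in oligodendrocyte-like nuclei (72.2 to 277). Tet1 (chromosome 10, 62804570 to 62908996), which oxidises 5mC to 5hmC, was at 19.9 CPM in excitatory-like nuclei (17.3 to 22.8). It was at 38.8 CPM in inhibitory-like (26.9 to 54.2), 84.9 in astrocyte-like (38.8 to 161) and 120 CPM in oligodendrocyte-like nuclei (52.0 to 237). At a minimum of 500 genes the 36 astrocyte-like nuclei held no Tet1 UMI, which allows up to 83.1 CPM. Tet2 was at 75.4 CPM in excitatory-like (70.3 to 80.8) and 134 CPM in inhibitory-like nuclei (110 to 160). Tet3 was at 85.1 (79.7 to 90.8) and 65.1 CPM (49.3 to 84.3).

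Among all members of the 3 lists, Atrx was highest in both neuron classes, at 988 CPM in excitatory-like (969 to 1007) and 922 CPM in inhibitory-like nuclei (860 to 988). It was also highest in the glial classes, at 1122 CPM in astrocyte-like (929 to 1343), 1362 in OPC-like (1062 to 1721) and 1039 in oligodendrocyte-like nuclei (809 to 1315). Dnmt3a was the highest of the 7 writers found in both neuron classes and in astrocyte-like and oligodendrocyte-like nuclei. Polb, a base excision polymerase, was the highest of the 20 members of the TET list in excitatory-like (192 CPM) and inhibitory-like nuclei (235 CPM), and Ogt in astrocyte-like nuclei (273 CPM). Glial levels of Tet1, Tet2 and Tet3 rested on 3 to 18 UMIs per class. Between excitatory-like and inhibitory-like nuclei the writers had a median log2 ratio of -0.17 (percentile 40.4), the readers -0.07 (percentile 56.1) and the TET list -0.28 (-0.46 to -0.05, percentile 6.23), with Idh2 at -1.41 and Tet1 at -0.96 (-1.49 to -0.40) lowest. Under TMM scaling the readers' median was 0.17. A Dnmt3a UMI was seen in 31.3% of excitatory-like nuclei (median depth 1694 UMIs) and 13.1% of astrocyte-like nuclei (647 UMIs), and after thinning to 500 UMIs in 10.2% (9.43 to 11.03) and 6.4% (2.80 to 12.2), intervals that overlapped. Thinning left out 28 of 153 astrocyte-like nuclei and none of the excitatory-like ones. For a gene of neurons, Rbfox3, the thinned shares were 10.1% of excitatory-like and 1.6% of astrocyte-like nuclei.

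**Figure D3:**
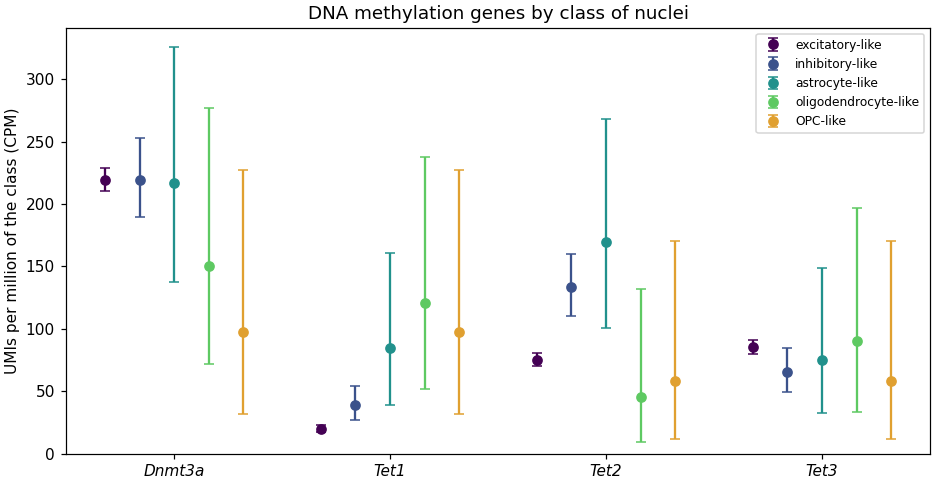
Level in CPM (vertical axis) of 4 genes of the DNA methylation lists (horizontal axis) in 5 classes of nuclei, with exact Poisson 95% intervals as bars. Dnmt3a lay at 219 CPM in both neuron classes, and Tet1 at 19.9 CPM in excitatory-like and 120 CPM in oligodendrocyte-like nuclei.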

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

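The minimum of 100 genes and every test in this part were chosen after the result was seen. Barcodes of the NeuN-negative library with at least 100 and under 300 detected genes entered no comparison between libraries or classes at the minimum of 300 and are given here for that reason, and 1092 of them were clustered with the deeper ones. Among them 268 were microglia-like (24.5%, 95% interval 22.0 to 27.2), 32 fibroblast-like (2.93%, 2.01 to 4.11), 29 endothelial-like (2.66%, 1.79 to 3.79) and 22 pericyte or smooth muscle-like (2.01%, 1.27 to 3.03). With at least 300 genes, 12 of 353 nuclei were microglia-like and no cluster of the other 3 classes formed. The microglia-like cluster carried Csf1r at 1279 CPM against 10.5 CPM in the other nuclei. The endothelial-like cluster carried Flt1 at 4382 against 24.4 CPM, and the pericyte or smooth muscle-like cluster Atp13a5 at 4145 against 75.3 CPM. The fibroblast-like name rested on 3 markers, Dcn, Col1a2 and Igf2, with 3, 9 and 7 UMIs.

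The oligodendrocyte-like and microglia-like shares were higher at a minimum of 100 genes (42.6% and 19.5%) than of 300 (27.8% and 3.40%). Empty droplets holding free RNA would give 1 profile to all shallow barcodes. Lists kept out of the clustering argue against this: in these barcodes, cholesterol and myelin lipid genes were 3.59-fold higher in oligodendrocyte-like than in other nuclei (2.78 to 4.71), and phagocytosis genes 12.7-fold higher in microglia-like nuclei (10.4 to 15.6). At the minimum of 100 genes, oligodendrocyte-like and microglia-like nuclei had medians of 281 and 200 UMIs, against 439.5 in astrocyte-like nuclei. Of these nuclei 15.4% of oligodendrocyte-like (12.6 to 18.5) and 5.30% of microglia-like (3.00 to 8.59) reached 300 genes. Among astrocyte-like nuclei 50% did (43.9 to 56.1). The classes thus held fewer UMIs per nucleus, but these rates and medians restate the shift and cannot test its cause. Whether the cells themselves yield fewer UMIs stays open. No biological explanation was tested.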

How the results depend on the processing

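Of 341 recomputed values, 262 stayed within the 95% counting interval of the reported value, 77 left it and another 2 left it with the opposite sign where that interval had excluded 0, and the minima of 200 and 100 genes and the removal of the highest 5% of Scrublet scores were chosen after seeing the data. With intervals set aside, 16 values had another sign than the reported one, 8 of them under TMM scaling. The excitatory-like share and the Rbfox3 ratio stayed inside their intervals under every alternative run for them, and so did the immediate early median between neuron classes except after thinning to 500 UMIs, where it was 1.15. The non-neuronal share of the NeuN-positive library was 0.0962% at 500 genes and 0% at 800 genes and in each library clustered alone at 300, 200 and 100 genes, where no glial cluster formed. The neuronal share of the NeuN-negative library was 15.2% at 500 genes, 100% of the 12 nuclei left at 800 genes and 1.52% at 100 genes. No glial cluster formed at 800 genes, so class shares of this library there do not measure its composition. The 16 nuclei named neuronal at 300 genes had a median of 590.5 genes and cannot account for all 12. The oligodendrocyte-like share was 45.7% at 500 genes, 0% at 800 genes, 35.9% at 200 genes and 42.6% at 100 genes. At 500 genes 26 of the 42 nuclei in that cluster were OPC-like at 300 genes, and no OPC-like cluster formed. Scaling by TMM moved the median of all genes by 0.60 between libraries and 0.23 between neuron classes, which is the cause of every TMM change because 1 factor applies to all genes. With TMM the list median between libraries was 0.73 for methylation writers, 0.26 for TET oxidation, 0.12 for 5mC and 5hmC readers, 0.56 for histone modifiers, 1.46 for ionotropic glutamate receptors and 2.41 for metabotropic glutamate receptors. It was 2.49 for GABA receptors, 1.98 for potassium channels, 3.01 for sodium and calcium channels, 2.13 for synaptic adhesion, 1.91 for immediate early genes and -0.47 for cholesterol and myelin lipids. It was -5.11 for phagocytosis, 0.79 for respiratory chain, 0.52 for ribosomal proteins, 2.40 for long noncoding RNAs and 1.51 for mitochondrial transcripts. Between neuron classes it was -0.048 for TET oxidation, 0.17 for 5mC and 5hmC readers, 0.079 for histone modifiers, 0.39 for ionotropic glutamate receptors, 1.35 for metabotropic glutamate receptors and 0.35 for GABA receptors. It was 0.77 for potassium channels, 0.39 for sodium and calcium channels, 0.31 for synaptic adhesion, -0.29 for respiratory chain, -0.17 for long noncoding RNAs and -0.12 for mitochondrial transcripts. The sign changes under TMM, among them those with an interval that had excluded 0 (the 5mC and 5hmC readers between libraries and the histone modifiers between neuron classes), followed from this shift of all genes and do not bear on those lists relative to other genes. At 500 genes the median of all genes moved by -0.37 between libraries. The list medians there were -0.63 for methylation writers, 0.42 for ionotropic glutamate receptors, 0.67 for metabotropic glutamate receptors, 1.21 for GABA receptors, 0.95 for potassium channels and 1.36 for sodium and calcium channels. It was 0.30 for immediate early genes, -7.15 for phagocytosis, -0.87 for ribosomal proteins and 0.81 for long noncoding RNAs. At 200 genes they were 2.11 for metabotropic glutamate receptors, 2.18 for GABA receptors, 1.85 for potassium channels, 1.88 for immediate early genes and -5.02 for phagocytosis. At 100 genes they were 2.35 for metabotropic glutamate receptors, 2.39 for GABA receptors, 2.40 for potassium channels and 2.73 for sodium and calcium channels. They were -6.21 for phagocytosis and 0.57 for mitochondrial transcripts. These channel and receptor medians were thus lower at 500 genes, where 15.2% of NeuN-negative nuclei were neuronal. They were higher at 100 genes, where 1.52% were. Whether the neuronal share moved them was not tested. With nuclei weighing equally the library medians were 2.03 for metabotropic glutamate receptors, 2.16 for GABA receptors and 1.95 for potassium channels. Between neuron classes the mean over nuclei gave -0.45 for mitochondrial transcripts. Without a UMI minimum the median of all genes moved by -1.75 between libraries and -0.51 between neuron classes. The library medians were then -0.61 for 5mC and 5hmC readers, 1.73 for potassium channels, -4.11 for phagocytosis and 1.11 for long noncoding RNAs. Between neuron classes this gave -0.17 for ionotropic glutamate receptors. Leaving mitochondrial genes and Malat1 out of the scaling gave -0.57 for 5mC and 5hmC readers. Removing the highest 5% of Scrublet scores gave 1.26 for metabotropic glutamate receptors. In astrocyte-like nuclei at 500 genes Tet1 was at 0 CPM, Tet2 at 83.1 CPM and Tet3 at 166 CPM. Thinned to 500 UMIs, the share of nuclei with a Dnmt3a UMI was 10.2% of excitatory-like, 10.4% of inhibitory-like and 6.4% of astrocyte-like nuclei, as fewer UMIs were drawn. The cause of the other changes was not tested. Class results were not recomputed in the other library, since none of the classes checked reached the set minimum of 50 nuclei there. The 253132 UMIs kept in the NeuN-negative library, where 1 UMI was worth 3.95 CPM, limited the precision. No paired analysis was possible because each group held 1 library.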

Other observations

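Of the tests in this part, those on glial clusters in the NeuN-positive library and the pooled immediate early ratios were chosen after the result was seen. Neuron subclasses were also compared by gene list, each against all other neurons of the NeuN-positive library. L6 IT-like nuclei had a median log2 ratio of 0.68 (0.34 to 1.13) for immediate early genes and 0.78 (0.33 to 1.02) for cholesterol and myelin lipid synthesis. L6 CT-like nuclei were at 0.59 (0.41 to 0.83) for immediate early genes and -0.71 (-0.78 to -0.52) for metabotropic glutamate receptors. For immediate early genes L6b-like nuclei were at -0.56 (-0.81 to -0.07) and the 917 excitatory-like nuclei led by Rorb and Pld5 at -0.44 (-0.87 to -0.27). In the same list Sst-like nuclei were at -1.22 (-1.60 to -0.63) and the other inhibitory-like nuclei at -1.92 (-2.24 to -1.38), against neurons that were mostly excitatory-like. For GABA receptors they were at -0.59 (-0.73 to -0.41) and -0.11 (-0.27 to 0.09). L5 ET-like nuclei, the neurons with long projections out of the cortex, were at 0.61 (0.20 to 0.87) for cholesterol and myelin lipid synthesis and 0.45 (0.11 to 0.57) for the nuclear-encoded respiratory chain. The pooled level of the immediate early list was also taken over the excitatory-like clusters of the NeuN-positive library clustered alone. It ranged from 417 CPM in L5/6 near-projecting (NP)-like nuclei to 3039 CPM in a cluster of 108 L2/3-like nuclei. That cluster was led by Pcsk1, Tnfaip6 and Tiparp, although list genes were no features of that clustering. L6b-like nuclei were there at 827 CPM, above L4-like (753), L5 IT-like (711) and L5 ET-like nuclei (668). They lay below L6 IT-like (1656) and L6 CT-like nuclei (1011). The low L6b-like median was thus not seen in the pooled level of that clustering.

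Of the 15 nuclei of glial clusters in the NeuN-positive library, 13 may be droplets with a neuron and a glial nucleus. Each held Syt1, Snhg11 and Kcnip4 together, with its interval, above 25% of their level in the neurons of that library (92.7% pooled over the 15, 85.4 to 100.5). A neuron placed in a glial cluster would pass this threshold too, so it cannot single out mixed droplets. In 1 oligodendrocyte-like nucleus, with 1 such UMI among 2322, the level lay below 25% and argues against a neuron in the droplet, and 1 astrocyte-like nucleus, with 3 such UMIs among 1323, could not be placed. Free neuronal RNA reaching all droplets alike is argued against by the markers of excitatory neurons, at 6.67 UMIs per nucleus against 1.64 in inhibitory-like nuclei, a 4.06-fold difference (3.27 to 5.00), while free RNA spread unevenly over droplets was not tested. The median of 2221 UMIs, 133% of the neurons' median (82.5 to 160), does not bear on it, since only 5 of 6221 neurons lay under 50% of that median in the deposited barcodes. The Scrublet caller had not worked on this library, so the share of single glial nuclei among the deposited barcodes may lie below 0.241%. No deposited barcode of this library had fewer than 745 UMIs or 509 genes. Glial nuclei of the NeuN-negative library had medians of 621 UMIs and 392 genes. Shallow glial nuclei could thus be missing here, and the glial share of the gate itself could lie higher. No biological explanation was tested.

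Immediate early genes were higher in excitatory-like than in inhibitory-like nuclei, and a candidate explanation was the cluster of 108 nuclei. Without it the list median was 1.46 (1.31 to 2.01), against 1.62 with it, which argues against that cluster as the whole cause. Depth per nucleus was the other explanation, with medians of 1694 and 1485 UMIs. Each of the 521 inhibitory-like nuclei was paired with the excitatory-like nucleus nearest in UMIs. The pooled log2 ratio of the list was 1.77 (1.53 to 2.01) in these pairs and 1.77 (1.56 to 1.98) over all nuclei. This argues against a larger share of these genes in deeper excitatory-like nuclei as the cause, and the pairs test no other effect of depth. Thinning to 500 UMIs decided nothing, since the list median of 1.15 (0.68 to 1.49) had 5 of 17 members at a bound and the pooled ratio of 1.60 (1.25 to 1.97) hardly depends on thinning. The state of the animals before dissection was not tested.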
